A study of Mus musculus with 20 samples.

How the data were processed

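RNA was measured in whole lungs of WT and VIPKO mice in normoxia or hypoxia, 20 libraries in 4 groups. Per the labels' protocols, total RNA was isolated with the RNeasy Mini Plus kit, and libraries were made from 1 µg with the NEBNext Ultra II Directional kit. Per the submitters' processing notes, reads were processed in Partek against mm10. The aligner, the counting strand, the normalization method and the Partek version are not given in the sources used here.

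The deposited table holds normalized gene values, used here as a signal, per the labels called normalized gene counts. It has 30746 lines, 55 of them without a gene name and 133 repeating a name. Within each library the low values fell on multiples of a smallest step, which was taken as the value of 1 read, so that deposited values were treated as an estimated count divided by 1 factor per library. The share of low values (up to 20 reads) within 0.05 reads of a whole number was 81.5% to 89.1% in 19 libraries and 41.4% in VIPKO hypoxia 2, where 77.7% lay near a multiple of 0.5. The step taken there need not be 1 read, its depth of 56.5 M is uncertain, and so whole reads are not claimed and no count model was run. Depth estimated from the step ran from 4.96 to 56.7 M reads, with a median of 17.8 M. The 10 highest genes took 9.58% to 15.5% of the signal. These depths and the limits set by a count of 0 (3 reads) cover counting error only.

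Values were taken as log2(signal + 1). Genes with at least 10 in at least 4 libraries were kept, which left 21658, of which 40 repeat a name. One linear model with 4 group means was fitted to all 20 libraries with limma 3.58.1 (R 4.3.3), with a variance trend, and 5 contrasts were tested. P-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. The 42 gene lists (568 genes) were written before the data were examined, as were the groups, tests and most alternatives. Lists were tested with camera, with a preset correlation of 0.01 and, as an alternative, an estimated correlation, and genes were also adjusted over the list alone. Single values were compared with exact permutation tests. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

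Genes were named by a rule fixed in advance. It took Vip first, then the 8 largest rises and 8 largest falls past the threshold with groups that did not overlap and a mean of at least 50 in the higher group. For the interaction it took 5 of each without the overlap condition. Unnamed gene models, immunoglobulin and T cell receptor segments and sex-linked genes were passed over. From each list it took up to 4 called genes by smallest p, or 2 as values where none was called. Coordinates come from the GENCODE vM21 annotation of GRCm38, in which 95.6% of the names matched 1 locus.

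The clock score is the mean log2 signal of the Dbp set minus that of the Arntl set. The transcript length and GC correction used 20982 tested genes with a length, or 96.9%. The simulation of shared controls first drew residuals with replacement and was changed, after that value was seen, to draws without replacement. The median r was 0.427 with replacement and 0.423 without.

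The steps were tested on simulated data of 21658 genes, with 200 changed per comparison. For VIPKO against WT in normoxia, 52% of 2-fold and 80% of 4-fold changes were recovered, and 5.33% of calls were false. These were 64%, 81% and 8.98% for hypoxia in WT and 57%, 82% and 7.10% in VIPKO. They were 61%, 80% and 4.64% for VIPKO against WT in hypoxia, and 39%, 70% and 1.72% for the interaction. These rates describe the simulated data, not the reported calls.

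Alternatives covered the pseudocount, the filter, rescaling, quantile normalization, the variance trend, library weights, fits on the compared groups alone, the replicate number as a block and leaving out each library. Alternatives added after seeing the data, among them voom weights on estimated reads, are listed below. No library was left out of the main results.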

Results

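Whole lungs of C57BL/6 mice were profiled by RNA sequencing in a design that crossed genotype with oxygen. Wild-type (WT) mice and mice labelled as VIP knockout (VIPKO) breathed room air (normoxia, 21% oxygen) or 10% oxygen for 4 weeks (hypoxia). The groups held 6 WT normoxia, 5 WT hypoxia, 4 VIPKO normoxia and 5 VIPKO hypoxia libraries. The genotype field of the labels calls the VIPKO samples a knockdown, while the sample titles and the design text call them a knockout. The labels do not state that each library came from a separate animal, so the p-values measure the spread between these samples.

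The estimated depth, in M reads, was 26.9, 13.1, 12, 56.7, 33.3 and 12.1 in WT normoxia libraries 1 to 6, and 25.5, 11.5, 14.7, 4.96 and 18.2 in WT hypoxia libraries 1 to 5. It was 21.1, 17.3, 17.1 and 17.5 in VIPKO normoxia libraries 1 to 4, and 55.8, 56.5, 19.5, 19.6 and 16.4 in VIPKO hypoxia libraries 1 to 5. Values are in units of signal after the submitters' normalization, and changes are log2 fold changes ± SE from limma with Benjamini-Hochberg adjusted p over 21658 genes.

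Vip encodes vasoactive intestinal peptide, a neuropeptide that relaxes airway and vascular smooth muscle. Its annotated locus is chromosome 10, 5639218 to 5647617 (GRCm38, mm10). The Vip signal in WT normoxia libraries 1 to 6 was 2.11, 12.7, 1.68, 5.17, 93.0 and 0, and in WT hypoxia libraries 1 to 5 it was 2.37, 6.77, 1.38, 0 and 3.43. In VIPKO normoxia libraries 1 to 4 it was 5.32, 5.54, 4.27 and 1.16, and in VIPKO hypoxia libraries 1 to 5 it was 2.17, 4.70, 1.08, 106 and 1.2. The highest value, 106, lay in the library labelled VIPKO hypoxia 4 and rested on 101 estimated reads. WT normoxia 5 had 155 estimated reads. A count of 0 allowed a signal of up to 4.72 in WT normoxia 6 and 11.7 in WT hypoxia 4, for counting error only. VIPKO minus WT was -15.0 in normoxia (2-sided exact permutation p = 0.695, 210 splits) and 20.2 in hypoxia (2-sided exact permutation p = 0.651, 252 splits). Without WT normoxia 5 the first was -0.266, and without the library labelled VIPKO hypoxia 4 the second was -0.504. Vip was near the floor in most libraries of both genotypes and went against the label of that library, so its signal did not bear out the genotype labels. Every genotype direction here rests on them, with that library kept under its label.

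Mitochondrial ribosomal RNA (mt-Rnr1 plus mt-Rnr2) was higher in VIPKO lungs. Its summed signal averaged 863 ± 673 (SD, n = 6) in WT normoxia, 2117 ± 2795 (SD, n = 5) in WT hypoxia, 18884 ± 6655 (SD, n = 4) in VIPKO normoxia and 6678 ± 2266 (SD, n = 5) in VIPKO hypoxia. The VIPKO mean was 21.9 times the WT mean in normoxia (exact permutation p = 0.00476 on log2 values, 2-sided) and 3.15 times in hypoxia (exact permutation p = 0.0317, 2-sided). Without WT hypoxia 5, whose mitochondrial ribosomal RNA was the highest of its group, the latter was 7.58 times (exact permutation p = 0.00794). Thymic genes stood out in VIPKO hypoxia 3, where Psmb11 was 248 times, Prss16 269 times and Foxn1 5.59 times the next library. Skeletal muscle genes stood out in WT hypoxia 5, where 11 of 12 were highest of all libraries and Acta1 reached 16163 against 385 in the next library.

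**Figure D1:**
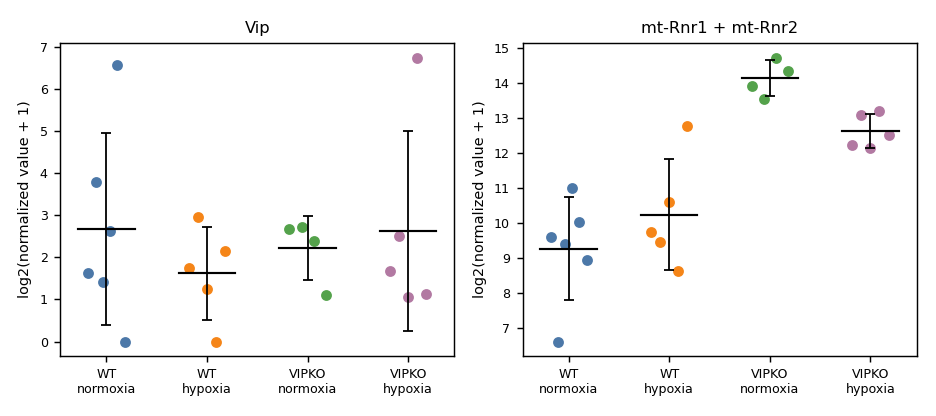
Log2(signal + 1) of Vip and of mitochondrial ribosomal RNA in each of the 4 groups, with points for libraries, lines for group means and bars of ±1 SD. Vip overlaps between genotypes, while mitochondrial ribosomal RNA in VIPKO normoxia averaged 18884 against 863 in WT normoxia.

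The first comparison asked what loss of VIP changed in lungs kept in room air, where the series title places spontaneous pulmonary arterial hypertension. Smad6, Bmp6 and Efnb2 fell, while Scgb3a1, Bpifa1, Rpl37 and mt-Rnr2 rose. Smad6, an inhibitory SMAD induced by BMP signals (chromosome 9, 63953076 to 64022059), fell by 1.00 ± 0.15 (adjusted p = 0.00194), from 4741 ± 376 (SD, n = 6) to 2372 ± 119 (SD, n = 4). The BMP ligand gene Bmp6 (chromosome 13, 38345107 to 38500302) fell by 0.63 ± 0.13 (adjusted p = 0.00720), from 4066 ± 639 (SD, n = 6) to 2602 ± 287 (SD, n = 4). The airway secretoglobin Scgb3a1 rose by 5.93 ± 1.14 (adjusted p = 0.00591).

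Among the 8 largest rises were both mitochondrial ribosomal RNAs, mt-Rnr2 (5.06 ± 0.76, adjusted p = 0.00197) and mt-Rnr1 (4.49 ± 0.62, adjusted p = 0.00179), and the mitochondrial subunit gene mt-Atp8 (3.80 ± 0.62, adjusted p = 0.00257). The small nucleolar RNA Snord15b rose by 5.04 ± 0.93 (adjusted p = 0.00496), the cytochrome P450 gene Cyp2a5 rose by 2.59 ± 0.45 (adjusted p = 0.00335) and the ribosomal protein gene Rpl38 rose by 2.18 ± 0.33 (adjusted p = 0.00197). The other two were H3f3c (2.12 ± 0.39, adjusted p = 0.00513) and Atp5k (2.02 ± 0.38, adjusted p = 0.00555). Cyp2a5, H3f3c and the ribosomal protein genes have near-identical copies, and how reads were assigned among them was not given, so their values are uncertain.

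Among the 8 largest falls, Sox18 codes for an endothelial transcription factor and fell by 0.89 ± 0.20 (adjusted p = 0.0117). Ankrd63 (chromosome 2, 118699103 to 118703963) fell by 1.17 ± 0.24 (adjusted p = 0.00763), from 546 ± 119 (SD, n = 6) to 239.6 ± 38.5 (SD, n = 4). The copper chaperone gene Sco2 fell by 2.10 ± 0.49 (adjusted p = 0.0145), and the prostaglandin D receptor gene Ptgdr2 fell by 1.46 ± 0.40 (adjusted p = 0.0280). The bacterial sensor gene Nod2 fell by 0.86 ± 0.20 (adjusted p = 0.0146), the immediate early gene Ier2 fell by 0.87 ± 0.25 (adjusted p = 0.0344), and Ccdc142 fell by 0.97 ± 0.26 (adjusted p = 0.0254). Smad6 completed the 8, and the groups of all 16 genes did not overlap. Calls were lost for Sco2 without VIPKO normoxia 2 (adjusted p = 0.0763) and VIPKO normoxia 3 (adjusted p = 0.0524), for Nod2 without VIPKO normoxia 2 (adjusted p = 0.0585) and VIPKO normoxia 4 (adjusted p = 0.0624), for Ccdc142 without WT normoxia 3 (adjusted p = 0.0559), VIPKO normoxia 2 (adjusted p = 0.0509) and VIPKO normoxia 4 (adjusted p = 0.121), for Ptgdr2 without WT normoxia 3, 4 or VIPKO normoxia 1, 2, 4 (adjusted p 0.05 to 0.110), and for Ier2 without WT normoxia 2, 3, 4 or VIPKO normoxia 2, 3, 4 (adjusted p 0.0574 to 0.111).

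Of the BMP and TGF-beta signalling genes, 5 of 24 fell, and 1 rose and 6 fell adjusted over the list alone. The median was -0.13 (camera adjusted p = 0.0181, or 0.792 with estimated correlation). Falls included Smad7 (-0.67 ± 0.14, adjusted p = 0.00763) beside Smad6 and Bmp6. The list call was lost without WT normoxia 2 or VIPKO normoxia 3 (adjusted p up to 0.0621). Of the arterial and venous endothelial genes, 4 of 15 fell, and 7 fell adjusted over the list alone, with a fall of the arterial ligand gene Efnb2 (-0.66 ± 0.14, adjusted p = 0.00822). The median was -0.36 (camera adjusted p = 0.00569, or 0.617 with estimated correlation). For potassium and calcium channels of the pulmonary artery, 1 of 13 fell, and 1 fell adjusted over the list alone, with a list call lost without WT normoxia 1, 2, 4 or VIPKO normoxia 2, 4 (adjusted p up to 0.123). The median was -0.24 (camera adjusted p = 0.0381, or 0.861 with estimated correlation). The natriuretic peptide receptor gene Npr1 fell by 0.46 ± 0.10 (adjusted p = 0.00780). Immediate early genes also shifted down, where 5 of 14 fell, and 5 fell adjusted over the list alone, including Jun (-0.58 ± 0.14, adjusted p = 0.0186). The median was -0.73 (camera adjusted p = 0.000686, or 0.792 with estimated correlation). The call was lost for Jun without VIPKO normoxia 2 (adjusted p = 0.0898) and VIPKO normoxia 4 (adjusted p = 0.0618). Smooth muscle contraction genes were not called, and 0 of 15 passed with limma (0 at an unadjusted p under 0.05), and 0 passed adjusted over the list alone. Of the VIP and PACAP ligand and receptor genes, 4 of 7 were measured and 0 passed over all genes with limma (1 at an unadjusted p under 0.05), while 1 fell adjusted over the list alone, Vipr2 at -0.70 ± 0.22 (adjusted p = 0.0548) over all genes.

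Of the airway club and ciliated genes, 10 of 15 rose, and 10 rose adjusted over the list alone. The median was 0.82 (camera adjusted p = 8.83e-07, or 0.617 with estimated correlation). Beside Scgb3a1, rises included Bpifa1 (5.58 ± 1.05, adjusted p = 0.00541), Reg3g (5.41 ± 1.05, adjusted p = 0.00599) and Muc5b (2.99 ± 0.60, adjusted p = 0.00693). Of the alveolar macrophage genes, 8 of 13 rose, and 11 rose adjusted over the list alone, including Ear2 (0.89 ± 0.22, adjusted p = 0.0178). The median was 0.87 (camera adjusted p = 2.84e-07, or 0.617 with estimated correlation). For neutrophils, 1 of 12 rose, and 4 rose adjusted over the list alone, namely the granule gene Ltf (2.76 ± 0.63, adjusted p = 0.0135). The median was 1.25 (camera adjusted p = 0.00168, or 0.792 with estimated correlation). For adipocyte genes, 2 of 11 rose, and 4 rose adjusted over the list alone, with Cfd (3.59 ± 0.86, adjusted p = 0.0166). The median was 1.94 (camera adjusted p = 0.000686, or 0.792 with estimated correlation). For cell cycle genes, all 23 had positive changes although 0 of 23 passed with limma (12 at an unadjusted p under 0.05), and 0 passed adjusted over the list alone. The median was 0.65 (camera adjusted p = 1.70e-05, or 0.792 with estimated correlation). Gene calls were lost for Ear2 without VIPKO normoxia 2 (adjusted p = 0.0704) and VIPKO normoxia 4 (adjusted p = 0.0764), for Ltf without VIPKO normoxia 2 (adjusted p = 0.0624), VIPKO normoxia 3 (adjusted p = 0.0507) and VIPKO normoxia 4 (adjusted p = 0.0504), and for Cfd without VIPKO normoxia 3 (adjusted p = 0.0628) and VIPKO normoxia 4 (adjusted p = 0.0599).

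Of the mitochondrial transcripts, 3 of 13 rose, and 5 rose adjusted over the list alone. The median was 0.69 (camera adjusted p = 6.80e-06, or 0.792 with estimated correlation). Of the cytosolic ribosomal protein genes, 9 of 23 rose, and 9 rose and 1 fell adjusted over the list alone, led by Rpl37 (1.21 ± 0.22, adjusted p = 0.00449), Rps24 (0.73 ± 0.14, adjusted p = 0.00564) and Rps6 (1.10 ± 0.24, adjusted p = 0.0108). The median was 0.38 (camera adjusted p = 4.51e-06, or 0.792 with estimated correlation). Changes ran against transcript length (Spearman's rho = -0.199) and GC content (-0.294) across genes, which are not independent replicates. For GC content rho was -0.306 for VIPKO against WT in hypoxia and 0.024 for the interaction. It was 0.299 for hypoxia in VIPKO and 0.186 in WT. With length and GC content corrected, 215 genes passed, 201 of them also called without the correction. With mitochondrial ribosomal RNA as a covariate, 0 genes passed with limma (2101 at an unadjusted p under 0.05), with the lowest adjusted p = 0.412 among the 60 named genes. Of these, 5 changed sign (mt-Rnr2, part of the covariate, Pgk1, mt-Nd6, mt-Nd4l and Rplp1), 37 kept at least 0.5 of their log2 fold change and 18 kept less. Smad6 was -1.24, Efnb2 -0.79, Rpl37 1.55, Cyp2a5 2.14 and Rps6 0.02. Without VIPKO normoxia 2, VIPKO normoxia 3 and VIPKO hypoxia 2, the libraries with the fewest whole-read values, 0 passed with limma (3091 at an unadjusted p under 0.05). These 3 stood apart from all others on the first principal component (21.0% of variance), at -59.2, -75.4 and -65.4 against -33.6 or above, although one was in hypoxia. On the second (15.5%), VIPKO normoxia 4 lay with them (-53.3), while VIPKO normoxia 1 (28.2) lay among the WT normoxia libraries. Removal left 2 VIPKO normoxia libraries, so the trait and the smaller group were not separated.

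In all, 1873 genes passed an adjusted p of 0.05, 1015 higher and 858 lower in VIPKO lungs. Of these, 359 changed more than 2-fold, 297 higher and 62 lower. The 2 groups did not overlap for 2138 genes, or 9.87% of those tested, where chance gives 0.952%. The count fell to 1127, 1239 and 1189 without WT normoxia 3, 4 and 6. It fell to 359, 889 and 443 without VIPKO normoxia 2, 3 and 4. The other 31 of 42 lists were not called by camera, and with an estimated correlation 0 were called (3 at an unadjusted p under 0.05).

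The second comparison asked how WT lungs responded to hypoxia. Plvap, Kdr and Pax5 fell, while Ccl21a, Tpi1, Sftpb, Scgb3a1 and Adipoq rose. Plvap, the protein of endothelial diaphragms (chromosome 8, 71497765 to 71511752), fell by 1.52 ± 0.17 (adjusted p = 0.000182), to 2168 ± 725 (SD, n = 5) from 5938 ± 361 (SD, n = 6), and was 2.86-fold lower. The lymphatic chemokine gene Ccl21a rose by 1.28 ± 0.18 (adjusted p = 0.000832), from 863 ± 143 (SD, n = 6) to 2156 ± 629 (SD, n = 5). The hypoxia-induced gene Ndrg1 rose by 0.76 ± 0.12 (adjusted p = 0.00175).

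Among the 8 largest rises, airway secretory genes were Scgb3a1 (6.88 ± 1.07, adjusted p = 0.00156) and Bpifb1 (5.63 ± 1.00, adjusted p = 0.00300), and mucosal genes were Gp2 (6.10 ± 0.94, adjusted p = 0.00149) and Tff2 (4.95 ± 0.87, adjusted p = 0.00286). Adipocyte genes were Cfd (5.52 ± 0.80, adjusted p = 0.00117), Plin1 (5.02 ± 0.85, adjusted p = 0.00234) and Retn (4.98 ± 0.69, adjusted p = 0.000817), and the developmental transcription factor gene Pax9 rose by 4.18 ± 0.89 (adjusted p = 0.00774). The 8 largest falls began with Ankrd63 (-2.27 ± 0.23, adjusted p = 4.64e-05), from 546 ± 119 (SD, n = 6) to 116 ± 39.0 (SD, n = 5), or 4.81-fold lower. The lactate transporter gene Slc5a12 fell by 1.78 ± 0.45 (adjusted p = 0.0157), the matrix protease gene Adamts9 fell by 1.68 ± 0.24 (adjusted p = 0.00117) and the fatty acid receptor gene Ffar1 fell by 1.66 ± 0.35 (adjusted p = 0.00724). Falls of Olfm2 (-1.61 ± 0.37, adjusted p = 0.0107), Plvap, Pitpnm2os2 (-1.48 ± 0.25, adjusted p = 0.00221) and the long noncoding RNA Morrbid (-1.39 ± 0.21, adjusted p = 0.00129) completed the 8. The strand used in counting was not given, so the antisense gene Pitpnm2os2 and Morrbid, which had no annotated locus here, are uncertain. All 16 genes kept their calls when any library was left out.

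**Figure D2:**
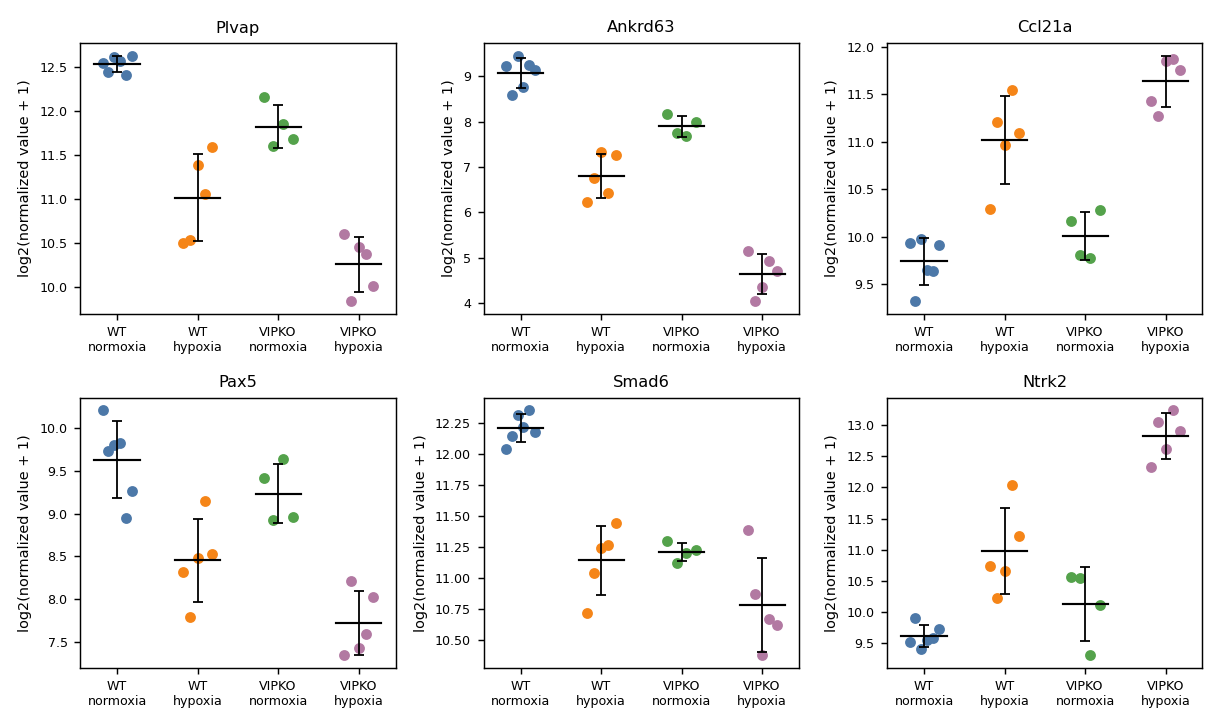
Log2(signal + 1) of Plvap, Ankrd63, Ccl21a, Pax5, Smad6 and Ntrk2 in the 4 groups, with points for libraries, lines for means and bars of ±1 SD. Plvap averaged 5938, 2168, 3663 and 1246 in WT normoxia, WT hypoxia, VIPKO normoxia and VIPKO hypoxia.

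Of the glycolysis genes, 12 of 16 rose, and 13 rose and 1 fell adjusted over the list alone, including Tpi1 (0.73 ± 0.14, adjusted p = 0.00406), Pfkl (0.65 ± 0.14, adjusted p = 0.00903) and Aldoa (0.78 ± 0.18, adjusted p = 0.0112). The median was 0.58 (camera adjusted p = 4.88e-07, or 0.327 with estimated correlation). The skeletal muscle signal of WT hypoxia 5 went with the highest glycolysis mean of its group, and the list passed without that library and VIPKO hypoxia 3 (adjusted p = 2.75e-06). Of the HIF target genes, 6 of 19 rose and 1 fell, and 7 rose and 1 fell adjusted over the list alone. The median was 0.31 (camera adjusted p = 0.0317, or 0.334 with estimated correlation). Bnip3 rose by 0.81 ± 0.18 (adjusted p = 0.00858) and the hexokinase gene Hk2 by 0.85 ± 0.22 (adjusted p = 0.0194), while Vegfa fell by 0.37 ± 0.09 (adjusted p = 0.0156). The HIF call was lost without WT normoxia 1 or WT hypoxia 2 (adjusted p up to 0.0640). Of the ribosomal protein genes, 11 of 23 rose, and 15 rose adjusted over the list alone, including Rpl4 (0.59 ± 0.11, adjusted p = 0.00308). The median was 0.55 (camera adjusted p = 4.82e-06, or 0.348 with estimated correlation).

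Of the capillary genes, 1 of 14 rose and 7 fell, and 1 rose and 9 fell adjusted over the list alone, including Fibin (-0.75 ± 0.13, adjusted p = 0.00246), Kdr (-0.57 ± 0.12, adjusted p = 0.00756) and Ednrb (-0.73 ± 0.14, adjusted p = 0.00554). The median was -0.47 (camera adjusted p = 0.000185, or 0.327 with estimated correlation). Of the lymphatic genes, 5 of 8 rose, and 6 rose adjusted over the list alone, including Mmrn1 (1.2 ± 0.20, adjusted p = 0.00240), Reln (1.08 ± 0.20, adjusted p = 0.00331) and Sema3d (0.77 ± 0.14, adjusted p = 0.00331). The median was 0.93 (camera adjusted p = 2.99e-05, or 0.300 with estimated correlation). Of the BMP and TGF-beta signalling genes, 1 of 24 rose and 5 fell, and 1 rose and 5 fell adjusted over the list alone. The list had 15 positive changes and was not called (median 0.13, camera adjusted p = 0.760). The ligand gene Bmp6 fell by 0.78 ± 0.12 (adjusted p = 0.00155), the co-receptor gene Eng fell by 0.85 ± 0.13 (adjusted p = 0.00124) and Smad6 fell by 1.06 ± 0.14 (adjusted p = 0.000649). The calcium channel gene Trpv4 rose by 0.42 ± 0.10 (adjusted p = 0.0123) and the chemokine gene Cxcl12 rose by 0.66 ± 0.16 (adjusted p = 0.0133). For fibrillar collagen and matrix, 2 of 21 fell, and 2 fell adjusted over the list alone, with Col6a3 (-0.98 ± 0.24, adjusted p = 0.0134), with a list call lost without WT normoxia 1, 4, 6 or WT hypoxia 1, 2 or VIPKO normoxia 1, 2, 3, 4 or VIPKO hypoxia 1, 2, 3 (adjusted p up to 0.691). The median was -0.35 (camera adjusted p = 0.0488, or 0.879 with estimated correlation).

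Of the B cell genes, 10 of 12 fell, and 10 fell adjusted over the list alone, including Bank1 (-1.15 ± 0.21, adjusted p = 0.00379) and Pax5 (-1.18 ± 0.23, adjusted p = 0.00550). The median was -0.97 (camera adjusted p = 3.98e-07, or 0.327 with estimated correlation). Of the natural killer cell genes, 4 of 10 fell, and 8 fell adjusted over the list alone, including the transcription factor gene Eomes (-1.29 ± 0.27, adjusted p = 0.00709). The median was -0.87 (camera adjusted p = 0.000202, or 0.327 with estimated correlation). For alveolar macrophages, 7 of 13 rose, and 10 rose and 1 fell adjusted over the list alone, including Siglecf (0.83 ± 0.19, adjusted p = 0.0101) and Ear2 (0.97 ± 0.20, adjusted p = 0.00703). The median was 0.81 (camera adjusted p = 0.000119, or 0.389 with estimated correlation). For neutrophils, 2 of 12 rose, and 2 rose adjusted over the list alone, with a list call lost without WT normoxia 2, 3, 6 or WT hypoxia 2, 3, 4 or VIPKO normoxia 3, 4 or VIPKO hypoxia 2, 3 (adjusted p up to 0.191). The median was 0.68 (camera adjusted p = 0.0488, or 0.879 with estimated correlation). Cell cycle genes shifted down, where 3 of 23 fell, and 3 fell adjusted over the list alone, with a list call lost without WT hypoxia 2 (adjusted p up to 0.0838). The median was -0.51 (camera adjusted p = 0.00881, or 0.879 with estimated correlation).

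Of the type 2 alveolar genes, 11 of 14 rose, and 13 rose adjusted over the list alone, including the surfactant genes Lpcat1 (0.57 ± 0.11, adjusted p = 0.00529), Sftpb (0.71 ± 0.15, adjusted p = 0.00894) and Napsa (0.64 ± 0.14, adjusted p = 0.00964) and the alarmin gene Il33 (0.83 ± 0.19, adjusted p = 0.0101). The median was 0.60 (camera adjusted p = 4.05e-08, or 0.300 with estimated correlation). Of the airway genes, 8 of 15 rose, and 14 rose adjusted over the list alone, including Bpifa1 (6.08 ± 0.98, adjusted p = 0.00184) and Tmem212 (1.14 ± 0.19, adjusted p = 0.00240). The median was 0.72 (camera adjusted p = 1.07e-08, or 0.300 with estimated correlation). Of the adipocyte genes, 9 of 11 rose, and 10 rose adjusted over the list alone, including Adipoq (5.33 ± 0.94, adjusted p = 0.00291). The median was 3.25 (camera adjusted p = 1.07e-08, or 0.300 with estimated correlation). For mesothelium, 0 of 8 passed with limma (4 at an unadjusted p under 0.05), and 3 rose adjusted over the list alone, with a list call lost without WT normoxia 1, 6 or WT hypoxia 1, 2 (adjusted p up to 0.103). The median was 0.60 (camera adjusted p = 0.0317, or 0.748 with estimated correlation). Clock genes shifted, where 3 of 16 rose and 1 fell, and 10 rose and 2 fell adjusted over the list alone, with a list call lost without WT normoxia 1 or WT hypoxia 2 (adjusted p up to 0.0674). The median was 0.78 (camera adjusted p = 0.0265, or 0.364 with estimated correlation). The clock score, the Dbp set minus the Arntl set, averaged 1.62 in WT normoxia and 3.53 in WT hypoxia (exact permutation p = 0.0281, adjusted p = 0.113 over 4 comparisons, 2-sided).

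In all, 3173 genes passed, 1707 higher and 1466 lower in hypoxia, and 802 changed more than 2-fold, 236 higher and 566 lower. Groups did not overlap for 1720 genes, or 7.94%, where chance gives 0.433%. The count was 2110 and 2074 without WT normoxia 2 and 4. It was 1737, 1382 and 1965 without WT hypoxia 1, 3 and 5. The share of higher calls was 53.8%, 48.6% with quantile normalization and 60.9% with the length and GC correction. With the clock covariate 58 of 93 named genes lost the call and 0 changed sign, among them Slc5a12, Ffar1, Kdr, Pax5, Sftpb, Lpcat1, Napsa, Il33, Bnip3, Hk2, Vegfa, Pfkl, Aldoa, Trpv4, Col6a3, Eomes, Siglecf and Ear2 (adjusted p 0.0501 to 0.167). The count with it was 543. Some changes kept their size (Slc5a12 -1.80, Il33 0.80) and some shrank (Hk2 0.57). Camera did not call the other 26 lists, and with an estimated correlation called 0 (4 at an unadjusted p under 0.05).

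The next comparison asked how VIPKO lungs responded to hypoxia. Plvap and Pax5 fell here too, and Ccl21a, Rgs5, Ntrk2, Lox and Nos3 rose. The VIPKO hypoxia group of this and the next tests holds the library with the high Vip signal. The neurotrophin receptor gene Ntrk2 (chromosome 13, 58806569 to 59133970) rose by 2.69 ± 0.29 (adjusted p = 3.45e-05), from 1188 ± 416 (SD, n = 4) to 7444 ± 1799 (SD, n = 5). Plvap fell by 1.57 ± 0.19 (adjusted p = 0.000142), to 1246 ± 264 (SD, n = 5), or 2.96-fold lower. The collagen crosslinking gene Lox rose by 1.32 ± 0.19 (adjusted p = 0.000758).

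The largest rise was of the pericyte signalling regulator Rgs5 (2.88 ± 0.35, adjusted p = 0.000119), followed by Ntrk2, the pentraxin gene Ptx3 (2.5 ± 0.36, adjusted p = 0.000758) and the transporter-family gene Slc26a10 (2.47 ± 0.28, adjusted p = 5.25e-05). Rises of Ptprr (2.27 ± 0.37, adjusted p = 0.00302), Lrrc3b (2.01 ± 0.44, adjusted p = 0.0280) and Snph (1.86 ± 0.31, adjusted p = 0.00374) and of the adrenomedullin receptor partner gene Ramp3 (1.78 ± 0.22, adjusted p = 0.000154) completed the 8. The largest fall was Ankrd63 (-3.26 ± 0.25, adjusted p = 4.38e-07), to 24.8 ± 7.65 (SD, n = 5) from 239.6 ± 38.5 (SD, n = 4), or 9.58-fold lower. The aryl hydrocarbon receptor target gene Cyp1a1 fell by 2.83 ± 0.52 (adjusted p = 0.00777), and the monocyte receptor gene Adgre4 fell by 1.73 ± 0.26 (adjusted p = 0.00136). Other falls were Slc5a12 (-2.39 ± 0.50, adjusted p = 0.0208), Cacna1i (-1.51 ± 0.31, adjusted p = 0.0185) and Lmntd1 (-1.42 ± 0.26, adjusted p = 0.00669), Plvap, and Pax5 (-1.51 ± 0.26, adjusted p = 0.00457), the B cell transcription factor. Calls were lost for Slc5a12 without VIPKO normoxia 3 (adjusted p = 0.108) and VIPKO normoxia 4 (adjusted p = 0.0580), for Cacna1i without VIPKO normoxia 3 (adjusted p = 0.105) and the library labelled VIPKO hypoxia 4 (adjusted p = 0.0551) and for Lrrc3b without VIPKO normoxia 3, 4 or VIPKO hypoxia 5 or the library labelled VIPKO hypoxia 4 (adjusted p 0.0628 to 0.136).

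Of the capillary genes, 4 of 14 fell, and 2 rose and 7 fell adjusted over the list alone, including Ednrb (-1.14 ± 0.16, adjusted p = 0.000624), Hpgd (-0.95 ± 0.14, adjusted p = 0.00105) and Fibin (-0.87 ± 0.14, adjusted p = 0.00334). The median was -0.32 (camera adjusted p = 1.16e-05, or 0.254 with estimated correlation). Of the lymphatic genes, 4 of 8 rose, and 5 rose adjusted over the list alone, including Ccl21a (1.63 ± 0.20, adjusted p = 0.000129), Reln (1.5 ± 0.22, adjusted p = 0.000905) and Prox1 (1.47 ± 0.25, adjusted p = 0.00374). The median was 0.90 (camera adjusted p = 3.88e-07, or 0.116 with estimated correlation). The endothelial nitric oxide synthase gene Nos3 rose by 0.88 ± 0.14 (adjusted p = 0.00334), the BMP ligand gene Bmp2 rose by 1.08 ± 0.18 (adjusted p = 0.00374) and Bmp6 fell by 0.69 ± 0.13 (adjusted p = 0.0114). Of the pulmonary artery channel genes, 1 of 13 rose, and 2 rose adjusted over the list alone, namely Trpv4 (0.91 ± 0.11, adjusted p = 0.000129), and the list call was lost without VIPKO normoxia 4 or VIPKO hypoxia 2 (adjusted p up to 0.0862). The median was 0.16 (camera adjusted p = 0.00904, or 0.690 with estimated correlation). Of the collagen and matrix genes, 2 of 21 rose, and 4 rose adjusted over the list alone, with Lox among them. The median was 0.25 (camera adjusted p = 0.00461, or 0.690 with estimated correlation). For fibroblasts and pericytes, 0 of 18 passed with limma (3 at an unadjusted p under 0.05), and 1 rose adjusted over the list alone, with a list call lost without WT normoxia 2, 3, 5 or WT hypoxia 5 or VIPKO normoxia 2, 4 or VIPKO hypoxia 2, 5 or the library labelled VIPKO hypoxia 4 (adjusted p up to 0.257). The median was 0.19 (camera adjusted p = 0.0482, or 0.781 with estimated correlation). The gene call was lost for Bmp6 without VIPKO normoxia 3 (adjusted p = 0.0625).

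Of the B cell genes, 8 of 12 fell, and 11 fell adjusted over the list alone, including Ighd (-1.56 ± 0.27, adjusted p = 0.00487), Blk (-1.26 ± 0.24, adjusted p = 0.00944) and Ms4a1 (-1.2 ± 0.23, adjusted p = 0.00944). The median was -1.22 (camera adjusted p = 1.02e-17, or 0.116 with estimated correlation). For natural killer cells, 0 of 10 passed with limma (9 at an unadjusted p under 0.05), and 9 fell adjusted over the list alone. The median was -1.08 (camera adjusted p = 4.37e-08, or 0.116 with estimated correlation). Neutrophil genes shifted up, where 0 of 12 passed with limma (8 at an unadjusted p under 0.05), and 7 rose adjusted over the list alone. The median was 1.51 (camera adjusted p = 1.03e-06, or 0.417 with estimated correlation). The chemokine gene Cxcl12 rose by 1.36 ± 0.18 (adjusted p = 0.000222). For HIF targets, 2 of 19 rose, and 5 rose adjusted over the list alone, with Ndrg1 (0.70 ± 0.13, adjusted p = 0.0108). The median was 0.26 (camera adjusted p = 0.00873, or 0.349 with estimated correlation). For glycolysis, 0 of 16 passed with limma (8 at an unadjusted p under 0.05), and 2 rose adjusted over the list alone. The median was 0.32 (camera adjusted p = 0.000117, or 0.690 with estimated correlation). For type 2 cells, 1 of 14 rose, and 2 rose adjusted over the list alone, namely the lipid synthesis gene Scd1 (1.44 ± 0.28, adjusted p = 0.0121). The median was 0.32 (camera adjusted p = 1.65e-05, or 0.417 with estimated correlation). Gene calls were lost for Blk without VIPKO normoxia 3 (adjusted p = 0.0625), for Ms4a1 without VIPKO normoxia 3 (adjusted p = 0.0609), and for Ndrg1 without VIPKO normoxia 3 (adjusted p = 0.0694).

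Further list calls were lost without single libraries. For immediate early genes, 0 of 14 passed with limma (4 at an unadjusted p under 0.05), and 3 rose adjusted over the list alone, with a list call lost without VIPKO hypoxia 1, 2 (adjusted p up to 0.116). The median was 0.33 (camera adjusted p = 0.00873, or 0.690 with estimated correlation). For erythroid genes, 0 of 12 passed with limma (1 at an unadjusted p under 0.05), and 0 passed adjusted over the list alone, with a list call lost without VIPKO normoxia 1 or VIPKO hypoxia 1, 2, 5 (adjusted p up to 0.0823). The median was 1.10 (camera adjusted p = 0.0161, or 0.690 with estimated correlation). For adipocytes, 0 of 11 passed with limma (0 at an unadjusted p under 0.05), and 0 passed adjusted over the list alone, with a list call lost without VIPKO normoxia 1 or VIPKO hypoxia 1 (adjusted p up to 0.143). The median was 0.96 (camera adjusted p = 0.0147, or 0.690 with estimated correlation). For mitochondrial transcripts, 0 of 13 passed with limma (2 at an unadjusted p under 0.05), and 0 passed adjusted over the list alone, with a list call lost without VIPKO normoxia 4 (adjusted p up to 0.0707). The median was -0.37 (camera adjusted p = 0.00413, or 0.690 with estimated correlation). Mitochondrial ribosomal RNA was lower in VIPKO hypoxia than in VIPKO normoxia (exact permutation p = 0.00794, 2-sided).

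In all, 216 genes passed, 133 higher and 83 lower in hypoxia, and 104 changed more than 2-fold, 53 higher and 51 lower. Groups did not overlap for 1112 genes, or 5.13%, where chance gives 1.59%. The count was 88 without VIPKO normoxia 3, 113 without VIPKO hypoxia 1, 392 without VIPKO hypoxia 2 and 118 without the library labelled VIPKO hypoxia 4. It was 134 with only the groups compared and 45 without VIPKO normoxia 2, VIPKO normoxia 3 and VIPKO hypoxia 2. The other 27 lists were not called by camera, and with an estimated correlation 0 were called (5 at an unadjusted p under 0.05).

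The hypoxia responses of the genotypes were compared across genes, which are not independent replicates. Fold changes had Pearson's r = 0.290 and Spearman's rho = 0.330. Among called genes, 44 rose in both genotypes, where independent lists would share 10.5, and 54 fell in both, where they would share 5.62. Opposite calls were made for 4 genes. Ankrd63, Plvap, Pax5, Ednrb and Fibin fell in both genotypes, and Ccl21a, Mmrn1, Reln, Cxcl12 and Trpv4 rose in both.

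A further comparison asked what loss of VIP changed in hypoxia, where the series title describes exaggerated disease. Dll4, Cyp1a1 and Ankrd63 fell, and Serpina3n, Ntrk2 and Slc26a10 rose. The Notch ligand gene of arterial endothelium, Dll4 (chromosome 2, 119325784 to 119335962), fell by 1.37 ± 0.18 (adjusted p = 0.000694), from 2010.0 ± 477 (SD, n = 5) to 771 ± 177 (SD, n = 5). The protease inhibitor gene Serpina3n rose by 1.37 ± 0.20 (adjusted p = 0.00295), and Ntrk2 rose by 1.85 ± 0.27 (adjusted p = 0.00295), from 2226 ± 1195 (SD, n = 5). Ankrd63 fell by 2.16 ± 0.24 (adjusted p = 0.000108), or 4.48-fold lower.

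The largest rises were of the neutrophil genes Ngp (2.95 ± 0.73, adjusted p = 0.0445) and S100a9 (2.59 ± 0.61, adjusted p = 0.0377) and of Wfdc21 (2.48 ± 0.62, adjusted p = 0.0472). Others were the matrix genes Hapln1 (1.62 ± 0.35, adjusted p = 0.0265) and Aspn (1.57 ± 0.33, adjusted p = 0.0246), and Slc26a10 (1.5 ± 0.26, adjusted p = 0.0136). The largest falls were Cyp1a1 (-2.59 ± 0.49, adjusted p = 0.0153), Ankrd63, Dll4, Fer1l4 (-1.35 ± 0.29, adjusted p = 0.0253) and the sphingosine-1-phosphate receptor gene S1pr5 (-1.27 ± 0.25, adjusted p = 0.0172). An AMP-activated kinase subunit gene followed as Prkag3 (-1.11 ± 0.19, adjusted p = 0.0107), with Unc79 (-1.08 ± 0.24, adjusted p = 0.0301) and Adgre4 (-1.03 ± 0.25, adjusted p = 0.0421). Ntrk2, Slc26a10, Serpina3n, Cyp1a1, Ankrd63, Dll4, S1pr5 and Prkag3 kept their calls when any library was left out, and Serpina3n, Ankrd63 and Dll4 in every setting tried. Calls were lost for Ngp without WT normoxia 1, 3, 4, 6 or WT hypoxia 1, 2, 3, 5 or VIPKO normoxia 1, 4 or VIPKO hypoxia 1, 2, 5 or the library labelled VIPKO hypoxia 4 (adjusted p 0.0509 to 0.0949), Wfdc21 without WT normoxia 1, 4, 5, 6 or WT hypoxia 1, 2, 3, 4, 5 or VIPKO normoxia 1, 4 or VIPKO hypoxia 1, 2, 5 or the library labelled VIPKO hypoxia 4 (adjusted p 0.0514 to 0.1) and Adgre4 without WT normoxia 3, 4, 6 or WT hypoxia 1, 2, 3 or VIPKO normoxia 2, 4 or VIPKO hypoxia 1, 2, 5 or the library labelled VIPKO hypoxia 4 (adjusted p 0.0505 to 0.101). They were also lost for S100a9 without WT hypoxia 1, 2, 3, 5 or VIPKO hypoxia 1, 2 (adjusted p 0.0530 to 0.0816), Hapln1 without WT hypoxia 1, 3 or VIPKO hypoxia 1, 2, 5 or the library labelled VIPKO hypoxia 4 (adjusted p 0.0513 to 0.0730), Aspn without WT hypoxia 1, 2, 3 or VIPKO hypoxia 2, 5 or the library labelled VIPKO hypoxia 4 (adjusted p 0.0515 to 0.0721), Fer1l4 without WT hypoxia 1, 3 or VIPKO hypoxia 2, 5 or the library labelled VIPKO hypoxia 4 (adjusted p 0.0502 to 0.0721) and Unc79 without WT hypoxia 1 or VIPKO hypoxia 1, 2 or the library labelled VIPKO hypoxia 4 (adjusted p 0.0507 to 0.0743).

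Of the neutrophil genes, 3 of 12 rose, and 11 rose adjusted over the list alone. The median was 2.10 (camera adjusted p = 3.34e-08, or 0.975 with estimated correlation). Of the fibrillar collagen and matrix genes, 3 of 21 rose, and 5 rose adjusted over the list alone, and all 21 had positive changes. The median was 0.49 (camera adjusted p = 5.07e-07, or 0.975 with estimated correlation). The fibronectin gene Fn1 rose by 0.79 ± 0.17 (adjusted p = 0.0286) and Lox rose by 0.95 ± 0.18 (adjusted p = 0.0153). Of the cell cycle genes, 2 of 23 rose, and 17 rose adjusted over the list alone, and all 23 had positive changes, including Mki67 (1.14 ± 0.25, adjusted p = 0.0265). The median was 0.89 (camera adjusted p = 1.73e-10, or 0.975 with estimated correlation). VIPKO hypoxia 3, with the thymic genes, had the highest cell cycle mean and Mki67 signal of its group, and without it the list median was 0.65 (camera adjusted p = 3.34e-05). Of the smooth muscle contraction genes, 1 of 15 rose, and 1 rose adjusted over the list alone, namely Cald1 (0.66 ± 0.13, adjusted p = 0.0193), and the list call was lost without WT hypoxia 1 (adjusted p up to 0.166). The median was 0.63 (camera adjusted p = 0.00172, or 0.975 with estimated correlation). For B cells all 12 changes were negative, and 0 of 12 passed with limma (4 at an unadjusted p under 0.05), and 0 passed adjusted over the list alone. The median was -0.47 (camera adjusted p = 0.000846, or 0.975 with estimated correlation). The chemokine gene Cx3cl1 fell by 0.83 ± 0.15 (adjusted p = 0.0146). Among these, calls were lost for Fn1 without WT hypoxia 1, 2, 3 or VIPKO hypoxia 1, 2, 5 or the library labelled VIPKO hypoxia 4 (adjusted p 0.0569 to 0.0709), Lox without VIPKO hypoxia 2 (adjusted p = 0.0530), Mki67 without WT hypoxia 1, 2, 3 or VIPKO hypoxia 5 or the library labelled VIPKO hypoxia 4 (adjusted p 0.0588 to 0.0742) and Cald1 without WT hypoxia 1, 3 or VIPKO hypoxia 2 or the library labelled VIPKO hypoxia 4 (adjusted p 0.0513 to 0.0589).

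In all, 350 genes passed, 155 higher and 195 lower in VIPKO lungs, and 74 changed more than 2-fold, 57 higher and 17 lower. Groups did not overlap for 814 genes, or 3.76%, where chance gives 0.794%. Without WT hypoxia 1, 2, 3 and 4 the count was 102, 194, 76 and 588. Without VIPKO hypoxia 1, 2, 3 and 5 it was 189, 35, 1339 and 143. It was 79 without the library labelled VIPKO hypoxia 4. The count was 9 with only the groups compared, 25 with the mitochondrial RNA covariate, 65 with the clock covariate and 109 with the length and GC correction, which moved the share of higher calls from 44.3% to 56.9%. VIPKO hypoxia 3 is the library with the thymic genes, and its T cell and thymus lists were the highest of its group. The other 37 lists were not called by camera, and with an estimated correlation 0 were called (1 at an unadjusted p under 0.05). Knockout effects in normoxia and hypoxia had Pearson's r = 0.213 across genes, with 35 genes higher in both against 7.26 for independent lists and 35 lower in both against 7.73.

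**Figure D3:**
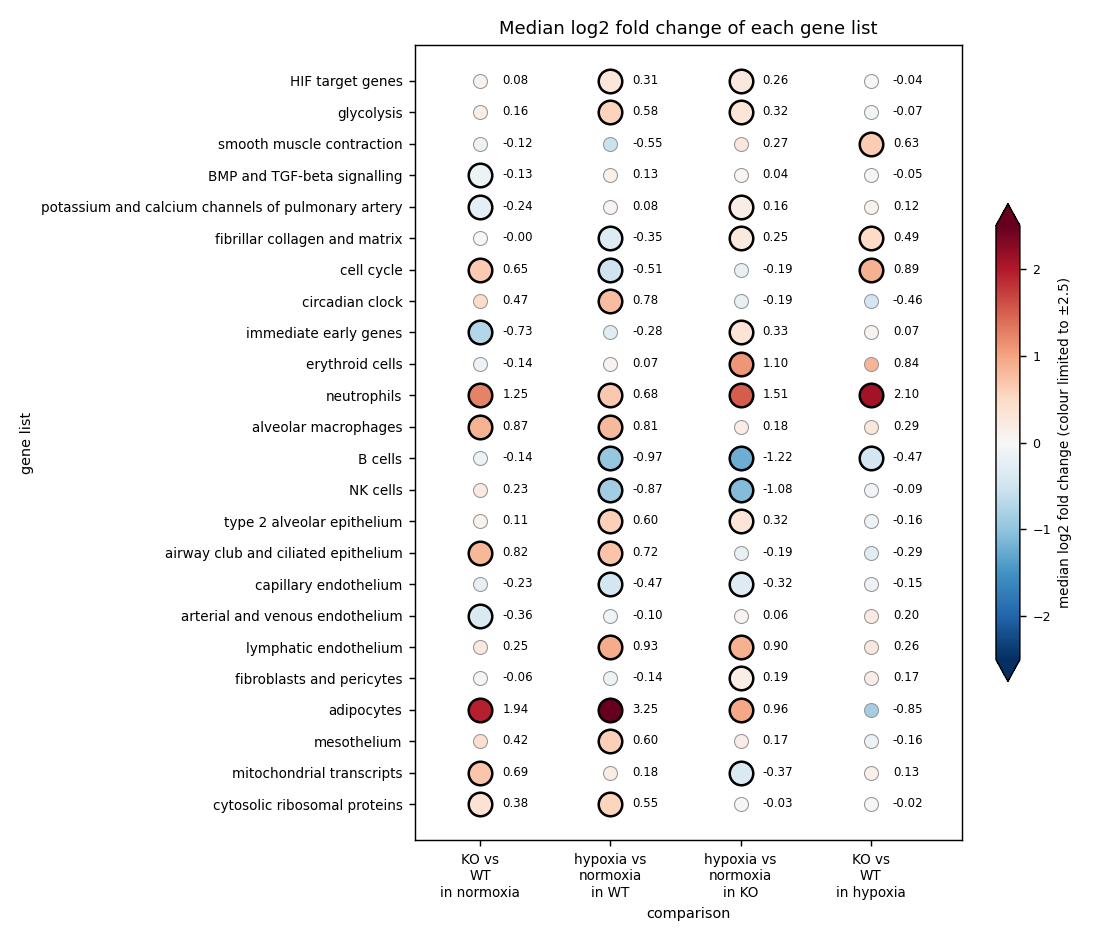
Median log2 fold change of 24 gene lists (vertical axis) in the 4 pairwise comparisons (horizontal axis), as points coloured up to ±2.5. Large points with black edges passed a camera adjusted p of 0.05 with the preset correlation, as did airway genes in WT hypoxia (0.72) and B cell genes in VIPKO hypoxia (-1.22).

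The last test asked whether the response to hypoxia differed between genotypes, as the difference of the log2 fold changes, VIPKO minus WT. Vegfc, Fst and Lox had a more positive response in VIPKO lungs, and Bpifa1 and Cyp2a5 a more negative one. The lymphatic growth factor gene Vegfc (chromosome 8, 54077606 to 54187096) had a difference of 1.26 ± 0.21 (adjusted p = 0.0179). Its means were 240.1 ± 56.2 (SD, n = 6) in WT normoxia, 281 ± 25.6 (SD, n = 5) in WT hypoxia, 227 ± 32.1 (SD, n = 4) in VIPKO normoxia and 649.6 ± 102 (SD, n = 5) in VIPKO hypoxia. Follistatin, an activin-binding protein, had a difference of 1.63 ± 0.25 (adjusted p = 0.0163) for its gene Fst. That of Lox was 1.23 ± 0.25 (adjusted p = 0.0397), where means went from 1049 to 2638 in VIPKO lungs and from 1302 to 1388 in WT lungs.

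Serpina3n and the endothelial lipase gene Lipg were the other two most positive, as Serpina3n (1.43 ± 0.29, adjusted p = 0.0384) and Lipg (1.03 ± 0.22, adjusted p = 0.0498). The most negative were Bpifa1 (-6.87 ± 1.46, adjusted p = 0.0480), Cyp2a5 (-4.28 ± 0.63, adjusted p = 0.0117), Sult1d1 (-3.18 ± 0.59, adjusted p = 0.0293), Serpina9 (-2.94 ± 0.60, adjusted p = 0.0397) and Adh7 (-2.31 ± 0.49, adjusted p = 0.0438). Fst and Cyp2a5 kept their calls when any library was left out, and the Vegfc call was lost without VIPKO normoxia 4 (adjusted p = 0.0567). Calls were lost for Serpina3n without WT normoxia 1, 2, 3, 4 or WT hypoxia 1, 3 or VIPKO normoxia 3, 4 or VIPKO hypoxia 1, 5 or the library labelled VIPKO hypoxia 4 (adjusted p 0.0530 to 0.115), Lox without WT normoxia 1, 2, 3, 4, 5, 6 or WT hypoxia 1, 3, 5 or VIPKO normoxia 2, 3, 4 or VIPKO hypoxia 1, 2, 5 or the library labelled VIPKO hypoxia 4 (adjusted p 0.0502 to 0.110), Lipg without WT normoxia 1, 2, 3, 4, 6 or WT hypoxia 1, 2, 3, 5 or VIPKO normoxia 2, 3, 4 or VIPKO hypoxia 1, 2, 5 or the library labelled VIPKO hypoxia 4 (adjusted p 0.0538 to 0.144) and Bpifa1 without WT normoxia 1, 2, 3, 4, 6 or WT hypoxia 1, 2, 3 or VIPKO normoxia 2, 3, 4 or VIPKO hypoxia 1, 2, 5 or the library labelled VIPKO hypoxia 4 (adjusted p 0.0610 to 0.140). They were also lost for Sult1d1 without WT normoxia 3, 4 or WT hypoxia 1, 3 or VIPKO normoxia 2, 3, 4 or VIPKO hypoxia 1, 2, 5 or the library labelled VIPKO hypoxia 4 (adjusted p 0.0508 to 0.101), Serpina9 without WT normoxia 1, 2, 3, 4, 6 or WT hypoxia 1, 3 or VIPKO normoxia 2, 3, 4 or VIPKO hypoxia 1, 2, 5 or the library labelled VIPKO hypoxia 4 (adjusted p 0.0540 to 0.124) and Adh7 without WT normoxia 1, 2, 3, 4, 6 or WT hypoxia 1, 3 or VIPKO normoxia 2, 3, 4 or VIPKO hypoxia 1, 2, 5 or the library labelled VIPKO hypoxia 4 (adjusted p 0.0574 to 0.140).

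**Figure D4:**
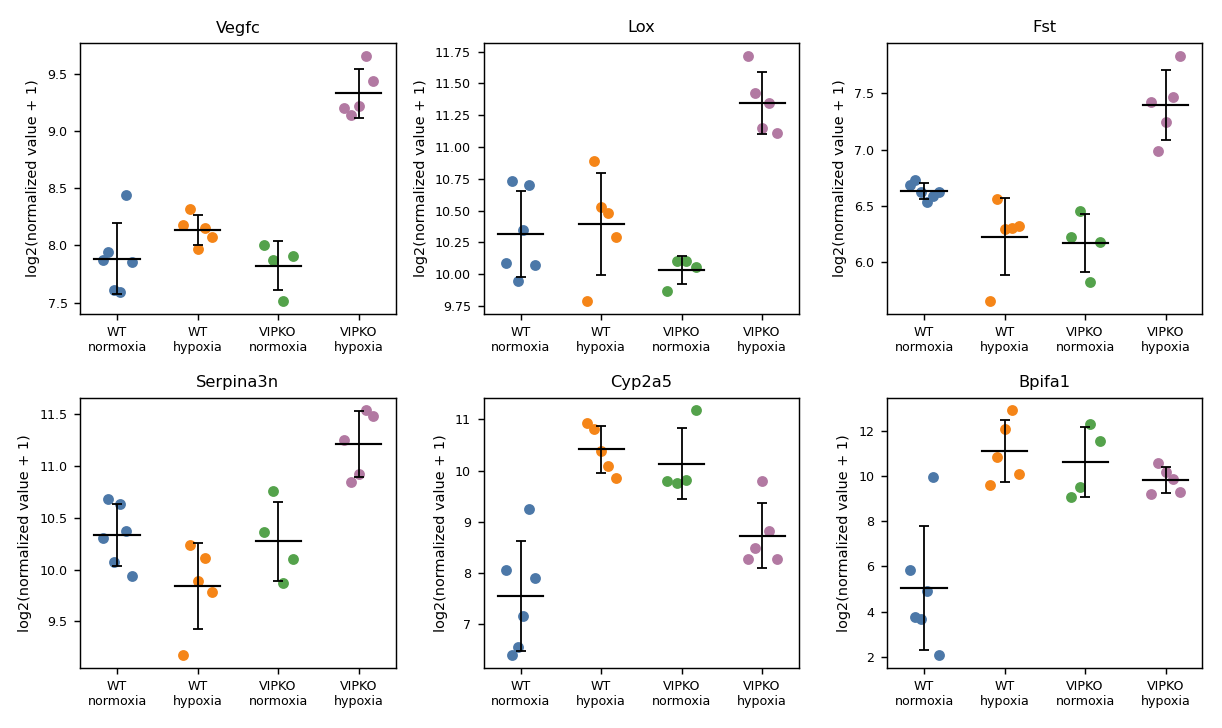
Log2(signal + 1) of Vegfc, Lox, Fst, Serpina3n, Cyp2a5 and Bpifa1 in the 4 groups, with points for libraries, lines for means and bars of ±1 SD. Vegfc averaged 227 in VIPKO normoxia and 649.6 in VIPKO hypoxia, against 240.1 and 281 in WT lungs.

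By camera with the preset correlation, some lists had a more positive response in VIPKO lungs. Of the collagen and matrix genes, 1 of 21 was more positive, and 3 were more positive adjusted over the list alone, with Lox among them. The median was 0.60 (camera adjusted p = 2.27e-05, or 0.852 with estimated correlation). For smooth muscle contraction, 0 of 15 passed with limma (2 at an unadjusted p under 0.05), and 0 passed adjusted over the list alone, with a list call lost without WT hypoxia 1 (adjusted p up to 0.0689). The median was 0.73 (camera adjusted p = 0.00373, or 0.876 with estimated correlation). For pulmonary artery channels, 0 of 13 passed with limma (2 at an unadjusted p under 0.05), and 1 was more positive adjusted over the list alone, with a list call lost without WT hypoxia 1 (adjusted p up to 0.101). The median was 0.41 (camera adjusted p = 0.0139, or 0.852 with estimated correlation). For immediate early genes, 0 of 14 passed with limma (5 at an unadjusted p under 0.05), and 0 passed adjusted over the list alone. The median was 0.71 (camera adjusted p = 0.000874, or 0.852 with estimated correlation).

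Other lists had a more negative response. Of the airway genes, all 15 differences were negative, and 2 of 15 were more negative, and 11 were more negative adjusted over the list alone, with Bpifa1 and Tmem212 (-1.41 ± 0.29, adjusted p = 0.0397). The median was -1.03 (camera adjusted p = 1.13e-10, or 0.482 with estimated correlation). A call was also lost for Tmem212 without WT normoxia 2, 3, 4, 6 or WT hypoxia 1, 2, 3 or VIPKO normoxia 2, 3, 4 or VIPKO hypoxia 1, 2, 5 or the library labelled VIPKO hypoxia 4 (adjusted p 0.0530 to 0.124). For adipocytes, 0 of 11 passed with limma (5 at an unadjusted p under 0.05), and 5 were more negative adjusted over the list alone. The median was -2.10 (camera adjusted p = 2.78e-05, or 0.852 with estimated correlation). For alveolar macrophages, 0 of 13 passed with limma (3 at an unadjusted p under 0.05), and 1 was more negative adjusted over the list alone. The median was -0.71 (camera adjusted p = 0.000906, or 0.852 with estimated correlation). For ribosomal proteins, 0 of 23 passed with limma (13 at an unadjusted p under 0.05), and 8 were more negative adjusted over the list alone. The median was -0.50 (camera adjusted p = 1.18e-05, or 0.852 with estimated correlation).

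More negative responses also appeared for mitochondrial transcripts, where 0 of 13 passed with limma (1 at an unadjusted p under 0.05), and 0 passed adjusted over the list alone, with a list call lost without WT hypoxia 5 (adjusted p up to 0.0582). The median was -0.56 (camera adjusted p = 0.00236, or 0.852 with estimated correlation). For type 2 cells, 0 of 14 passed with limma (1 at an unadjusted p under 0.05), and 0 passed adjusted over the list alone, with a list call lost without WT normoxia 2, 3, 6 or WT hypoxia 1, 3, 5 or VIPKO normoxia 2, 4 or VIPKO hypoxia 2, 5 or the library labelled VIPKO hypoxia 4 (adjusted p up to 0.127). The median was -0.26 (camera adjusted p = 0.0490, or 0.852 with estimated correlation). For clock genes, 0 of 16 passed with limma (10 at an unadjusted p under 0.05), and 2 were more positive and 5 were more negative adjusted over the list alone, with a list call lost without WT normoxia 1 or WT hypoxia 2 or VIPKO normoxia 1 or VIPKO hypoxia 3 or the library labelled VIPKO hypoxia 4 (adjusted p up to 0.0878). The median was -1.07 (camera adjusted p = 0.0327, or 0.852 with estimated correlation).

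In all, 61 genes passed, 29 with a more positive and 32 with a more negative response, and 33 differed more than 2-fold, 8 more positive and 25 more negative. At an unadjusted p under 0.05 there were 3082. Without WT normoxia 1, 3, 4 and 6 the count was 37, 15, 7 and 35. Without WT hypoxia 1, 3 and 4 it was 12, 14 and 541. Without VIPKO normoxia 1, 2, 3 and 4 it was 155, 13, 27 and 4. Without VIPKO hypoxia 1, 2, 3 and 5 it was 8, 27, 364 and 25. It was 9 without the library labelled VIPKO hypoxia 4. With limma, 0 passed with the mitochondrial RNA covariate (2118 at an unadjusted p under 0.05), with the clock covariate (2120) or without VIPKO normoxia 2, VIPKO normoxia 3 and VIPKO hypoxia 2 (1886). The other 31 lists were not called by camera, and with an estimated correlation 0 were called (1 at an unadjusted p under 0.05).

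A final comparison asked whether VIPKO lungs in normoxia resembled WT lungs in hypoxia. Both were measured against the same WT normoxia libraries, which raises the correlation by itself. Across genes, Pearson's r was 0.357 and Spearman's rho 0.384, while unchanged groups simulated against the same controls gave a median r of 0.423 (-0.377 to 0.748), with 65 of 100 draws at or above the observed r. With the controls split between the comparisons, r averaged 0.213 (0.0881 to 0.325 over 20 splits). The covariance was 0.116, against a mean of 0.0761 with the controls split and a simulated 0.0494. Both comparisons called 280 genes higher, against 80.0 for independent lists, 198 lower, against 58.1, and 8 in opposite directions. Independent lists leave out the shared controls, so the excess does not measure a shared effect. Smad6, Bmp6 and Ankrd63 fell in both, and Scgb3a1, Bpifa1 and Reg3g rose in both.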

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

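Tests chosen only after the result was seen were the test of a single clock phase per group, the skeletal muscle test in WT hypoxia 5 and the value of mt-Rnr2 after the length and GC correction. A library was listed when its gap to the nearest of its group exceeded Dixon's 95% critical value. Of 432 groups tested, 48 (11.1%) held such a library, where chance gives about 5% or 1 in 20. In the next paragraphs each value stands against the median of the other libraries of its group, as a log2 mean for a gene list and log2(signal + 1) for a gene.

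WT normoxia 1 was highest for plasma cells (8.94 against 7.23) and lowest for Cyp1a1 (6.28 against 8.26). WT normoxia 2 was highest for calcineurin and NFAT (9.37 against 9.21) and lowest for glycolysis (9.87 against 10.17) and S100a9 (5.34 against 7.09). WT normoxia 3 was lowest for Wfdc21 (0 against 3.24). WT normoxia 5 was highest for neuroendocrine cells and nerves (3.78 against 2.87) and lymphatic endothelium (9.75 against 9.47). WT normoxia 6 was lowest for platelets and megakaryocytes (5.91 against 6.82). WT hypoxia 1 was highest for Fer1l4 (6.55 against 5.44) and Unc79 (9.54 against 8.12) and lowest for monocytes and interstitial macrophages (8.01 against 8.81), Ccdc142 (5.78 against 6.63) and Fst (5.65 against 6.31). WT hypoxia 4 was highest for immediate early genes (10.71 against 9.73), erythroid cells (10.59 against 8.13), Adamts9 (10.87 against 9.36) and Cacna1i (7.58 against 6.46) and lowest for clock score (0.86 against 4.13) and cytosolic ribosomal proteins (9.99 against 10.61). WT hypoxia 5 was highest for glycolysis (11.30 against 10.48), skeletal muscle (9.99 against 2.48), thymus (3.17 against 2.05), Snord15b (0.81 against 0) and Atp5k (7.83 against 6.12).

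VIPKO normoxia 1 was highest for estimated reads in M (21.1 against 17.3) and lowest for Gp2 (0 against 5.85) and Serpina9 (4.74 against 6.54). VIPKO normoxia 3 was highest for immediate early genes (10.06 against 9.51), skeletal muscle (4.43 against 2.91) and Olfm2 (6.40 against 5.34) and lowest for circadian clock (9.61 against 10.17). VIPKO normoxia 4 was highest for Cyp2a5 (11.19 against 9.79) and lowest for Ccdc142 (5.05 against 6.31). VIPKO hypoxia 1 was highest for skeletal muscle (5.61 against 3.26). VIPKO hypoxia 2 was highest for Slc26a10 (10.27 against 9.23). VIPKO hypoxia 3 was highest for T cells (9.77 against 6.48), thymus (9.23 against 2.41) and mesothelium (9.90 against 9.42) and lowest for smooth muscle contraction (9.33 against 10.20), nitric oxide, prostacyclin and cyclic nucleotide (9.16 against 9.58), capillary endothelium (11.02 against 11.37), Ffar1 (3.91 against 4.77) and Olfm2 (3.69 against 4.74). The library labelled VIPKO hypoxia 4 was highest for Vip (6.74 against 1.4) and Rgs5 (11.53 against 9.74) and lowest for clock score (0.0650 against 2.82) and circadian clock (9.57 against 10.10).

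The response to hypoxia differed between genotypes by the interaction test for 61 genes. Among those named, the difference in log2 fold change was 1.63 for Fst, 1.43 for Serpina3n, 1.26 for Vegfc, 1.23 for Lox, 1.03 for Lipg, -6.87 for Bpifa1, -4.28 for Cyp2a5, -3.18 for Sult1d1, -2.94 for Serpina9 and -2.31 for Adh7. The median difference of the called lists was 0.73 for smooth muscle contraction, 0.41 for potassium and calcium channels of pulmonary artery, 0.60 for fibrillar collagen and matrix, -1.07 for circadian clock, 0.71 for immediate early genes, -0.71 for alveolar macrophages, -0.26 for type 2 alveolar epithelium, -1.03 for airway club and ciliated epithelium, -2.10 for adipocytes, -0.555 for mitochondrial transcripts and -0.50 for cytosolic ribosomal proteins.

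For each comparison 100 splits into groups of the same sizes were counted, the real one included. Chance can be excluded for VIPKO against WT in normoxia, where 1 split called as many genes (1873 against at most 148 in the others), and for hypoxia in WT, where 1 did (3173 against at most 79). For the interaction 1 did (61 against at most 44), but permuting oxygen within genotype also removed its main effect, so chance stays open. For hypoxia in VIPKO 3 splits did (216 against at most 631). For VIPKO against WT in hypoxia 4 did (350 against at most 1861). Both shares are under 0.05, unadjusted over the 5 comparisons. Splits with several times the real count point to a structure of the samples other than the groups, so chance stays open.

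VIPKO normoxia lungs combined high mitochondrial ribosomal RNA with high values of short ribosomal protein genes. Fold changes fell with transcript length (rho = -0.199 across genes) and GC content (rho = -0.294). After the length and GC correction 215 genes passed. The median absolute log2 fold change of the calls went from 0.55 to 0.39 and the median SE from 0.135 to 0.140. Part of the calls may follow these trends. The correction left mt-Rnr2 at 4.73 (adjusted p = 0.0108), but a trend over all tested genes could shift it little, so its cause stays open. Mitochondrial RNA did not overlap between genotypes in normoxia, so as a covariate it cannot tell a library property from genotype. In the 10 hypoxia libraries its relation to the score of the called genes stayed open. Here r = 0.457 and rho = 0.455 (exact permutation p = 0.235 and 0.209), and r = 0.386 without WT hypoxia 4 and 5. A knockout effect and a difference in RNA quality or preparation stay untested, also for the 3 libraries with the fewest whole-read values.

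Clock genes differed between libraries within groups. Over 20 libraries the Dbp and Arntl sets moved in opposite directions within groups (r = -0.941, permutation p = 3e-05, rho = -0.758, permutation p = 0.00077, and r = -0.939 without the library labelled VIPKO hypoxia 4 and WT hypoxia 4), as sampling at different phases of the day could give. A single phase per group is argued against, since 3 of 4 groups span as much as the group means, each through a single library. An effect of hypoxia on the clock itself stays open, and the sources used give no sampling times.

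Adjacent tissue may have entered at least 2 libraries. VIPKO hypoxia 3 had the thymic epithelial genes Psmb11 and Prss16 at least 10 times the next library, beside thymocyte genes, as thymus would give. WT hypoxia 5 had 11 of 12 skeletal muscle genes highest, at a median of 29.4 times the next library, as muscle would give. Myh7 was not highest. Fat as a source of the adipocyte rises was not tested, nor any biological explanation.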

How the results depend on the processing

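The alternatives chosen after seeing the data were voom weights, leaving out VIPKO hypoxia 3 with WT hypoxia 5, leaving out VIPKO normoxia 2, VIPKO normoxia 3 and VIPKO hypoxia 2, the mitochondrial RNA and clock covariates, and the length and GC correction. Main counts of genes were 1873 (VIPKO against WT in normoxia), 3173 (hypoxia in WT), 216 (hypoxia in VIPKO), 350 (VIPKO against WT in hypoxia) and 61 (interaction). Except where a reason is given, the cause was not tested.

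Library weights gave 5448, 6590, 717, 1926 and 2228 in that order. VIPKO against WT in hypoxia gave 225 without the filter, 222 with no variance trend and 9 with only the groups compared. No variance trend gave 12 for the interaction. Only the groups compared, with fewer samples, gave 134 for hypoxia in VIPKO but 3118 in WT and 2201 in normoxia. Voom weights gave 599 in hypoxia and 275 for the interaction. Without VIPKO hypoxia 3 and WT hypoxia 5 these were 1065 and 292, with 11 lists called in hypoxia against 5.

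Without VIPKO normoxia 2, VIPKO normoxia 3 and VIPKO hypoxia 2, limma called 0 in normoxia (3091 at an unadjusted p under 0.05), 45 for hypoxia in VIPKO, 27 for VIPKO against WT in hypoxia and 0 for the interaction (1886 at an unadjusted p under 0.05), with fewer samples. With the mitochondrial RNA covariate, limma called 0 for VIPKO against WT in normoxia (2101 at an unadjusted p under 0.05), 1539 for hypoxia in WT, 25 for VIPKO against WT in hypoxia and 0 for the interaction (2118 at an unadjusted p under 0.05). In normoxia the covariate reversed mt-Rnr2, part of it (-0.31), Pgk1 (-0.036), mt-Nd6 (-0.16), mt-Nd4l (-0.17) and Rplp1 (-0.11). The clock covariate gave 923 for VIPKO against WT in normoxia, 543 for hypoxia in WT, 65 for VIPKO against WT in hypoxia and 0 for the interaction (2120 at an unadjusted p under 0.05). The length and GC correction gave 215 in normoxia, 109 for VIPKO against WT in hypoxia and 31 for the interaction, and moved the share of higher calls in normoxia from 54.2% to 71.6% and in hypoxia from 44.3% to 56.9%.

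Replicate numbers did not pair the libraries, since the 27 pairs with the same number had a mean correlation of -0.0075 and 7 libraries were closest to one with their own number. With the replicate number as a block, limma called 682, 1544, 90, 149 and 0 (2670 at an unadjusted p under 0.05).

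The resemblance of VIPKO normoxia to WT hypoxia (r = 0.357) was 0.429 with pseudocount 8, 0.457 with a filter at 50, 0.431 with quantile normalization and 0.456 with the length and GC correction. With an estimated correlation, camera called 0 lists in each of the 5 comparisons, against 11, 16, 15, 5 and 11, and unadjusted p under 0.05 held for 3, 4, 5, 1 and 1. Other settings ended single list calls. In normoxia, BMP signalling and artery channels were lost with quantile normalization, with the length and GC correction and without VIPKO normoxia 2, VIPKO normoxia 3 and VIPKO hypoxia 2, as were neutrophils and arterial endothelium without these 3. In WT hypoxia, HIF targets were lost with the first 2 of these, clock, neutrophils and mesothelium with the correction, and collagen without the 3. In VIPKO hypoxia, fibroblasts were lost with each, artery channels with the last 2, mitochondrial transcripts with the correction and erythroid cells without the 3. In the interaction, type 2 cells were lost with the last 2, clock with the correction, and clock and mitochondrial transcripts without VIPKO hypoxia 3 and WT hypoxia 5.

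Leaving out each library gave 359 to 2551, 1382 to 4710, 88 to 392, 35 to 1339 and 4 to 541 genes, and 9 to 12, 10 to 19, 11 to 21, 5 to 10 and 9 to 16 lists. The agreement of the hypoxia responses ranged from 0.176 to 0.379, the resemblance from 0.267 to 0.408, and the Vip difference from -18.9 to -0.266 in normoxia and from -0.504 to 25.7 in hypoxia. The hypoxia sign rests on the library labelled VIPKO hypoxia 4. Of 236 named results, 51 held in every setting. In the same order, 24 of 60, 58 of 93, 2 of 42, 21 of 30 and 11 of 11 calls were lost with the clock covariate, and 60, 25, 9, 24 and 11 with the mitochondrial RNA covariate. Over 4720 results with a library left out, 688 lost the call and 0 changed sign.

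For Vip, pseudocount 8 and the filter at 50 gave no value, since the test used the values themselves and Vip lay below that filter. A count model was not run, since values in VIPKO hypoxia 2 were not whole reads. Depth limits genes near the floor most in WT hypoxia 4, with 4.96 M estimated reads.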

Other observations

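The genes in this part come from lists written before the data were examined or from the rule by size, and no test here was chosen after its result was seen. In WT lungs hypoxia changed single genes of lists that were not called. The nerve intermediate filament gene Prph rose by 1.49 ± 0.37 (adjusted p = 0.0150). The serotonin-degrading enzyme gene Maoa rose by 0.35 ± 0.10 (adjusted p = 0.0284). The phosphodiesterase gene Pde5a fell by 0.69 ± 0.20 (adjusted p = 0.0259), and the proteoglycan gene Dcn rose by 1.07 ± 0.19 (adjusted p = 0.00334). The adhesion gene Vcam1 fell by 0.61 ± 0.14 (adjusted p = 0.00913). Calls were lost for Maoa without WT normoxia 2 (adjusted p = 0.0625) and WT hypoxia 3 (adjusted p = 0.0793) and Pde5a without WT normoxia 2 or WT hypoxia 1, 2, 3 (adjusted p 0.0506 to 0.0756).

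In VIPKO lungs hypoxia raised the angiotensinogen gene Agt by 1.78 ± 0.38 (adjusted p = 0.0264). Among chemokine genes, Cx3cl1 fell by 0.77 ± 0.16 (adjusted p = 0.0208) and Ccl5 fell by 1.21 ± 0.26 (adjusted p = 0.0281). The atrial natriuretic peptide gene Nppa did not pass in WT hypoxia, with 2.62 ± 0.97 (adjusted p = 0.0708). The interferon list was not called by camera in any comparison, and 1 of its genes rose adjusted over the list alone in VIPKO hypoxia. Y-linked genes were present in 4 of 6 WT normoxia, 2 of 5 WT hypoxia, 3 of 4 VIPKO normoxia and 2 of 5 VIPKO hypoxia libraries. Calls were lost for Agt without VIPKO normoxia 2, 4 or VIPKO hypoxia 1, 5 (adjusted p 0.0629 to 0.0896), Cx3cl1 without VIPKO normoxia 3 (adjusted p = 0.0554), VIPKO normoxia 4 (adjusted p = 0.0772) and VIPKO hypoxia 1 (adjusted p = 0.0614) and Ccl5 without VIPKO normoxia 3, 4 or VIPKO hypoxia 5 or the library labelled VIPKO hypoxia 4 (adjusted p 0.0571 to 0.141).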
